A study of Mus musculus with 14 samples.

How the data were processed

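RNA was measured in 14 libraries of primary mouse small cell lung cancer, 7 from tumours with Rb1 and Trp53 deleted (RP) and 7 with Crebbp deleted as well (RPC). Per the labels' protocols, cells were lysed in TRIzol, and polyadenylated RNA was selected and made into Illumina libraries with a NEBNext Ultra kit. Each deposited file gives raw read counts per gene, not normalized, with gene symbols as row names. Per the submitters' processing notes, bcl2fastq 1.8.2, TopHat2 2.0.12 and HTSeq 0.6.1 were used with the mm9 genome; their settings, the gene annotation and the use of strand are not given in the sources used here. HTSeq counts reads that map uniquely to a single gene, so genes with near-identical copies are undercounted, and without a known strand setting, reads of overlapping antisense genes cannot be told apart.

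The 5 rows of each file that name no gene were kept out of library sizes and tests. Reads outside annotated genes made up 15.1% to 20.5% of the counts in a file, reads with more than 1 alignment 8.4% to 11.2%, and reads between overlapping genes 0.88% to 1.09%. The remaining counts came to between 10060969 and 24052799 per library. No pair of libraries of 1 genotype was a repeat of the same library: chi-square per degree of freedom was at least 62.1 over 42 pairs.

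Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and tested with the quasi-likelihood F test of RPC against RP with no covariate, over all 14 libraries. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The printed SE of a log2 fold change is its size divided by the root of the F statistic. CPM values use library sizes scaled by TMM, and log2 CPM used a prior count of 2. Crebbp, Rb1, Trp53 and Ep300 were tested with an exact two-sided permutation test of mean log2 CPM over all splits of 14 libraries into 7 and 7, as were chromosome scores.

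Before the data were examined, 42 gene lists were fixed, 6 of them as the main question (tight junctions, adherens junctions and desmosomes, epithelial identity, mesenchymal, neuroendocrine and neuronal genes), with markers of the cell types a lung tumour sample could hold. The 37 lists with at least 3 tested genes were tested with camera of limma 3.58.1 (preset correlation 0.01), with camera and an estimated correlation, and with fry. Symbols follow the files, some of them older forms (Mycl1, Pvrl2), and 2 list members were not matched to a symbol in the files. Genes were named by a rule fixed at the same time: Crebbp, Rb1, Trp53 and Ep300; in each direction the 10 genes with the smallest p among called genes with an absolute log2 fold change of at least 1 and a mean of at least 1 CPM in the higher genotype, leaving out predicted genes and sex genes; 12 fixed genes; and up to 4 members of each list described, from those with the smallest p and the highest CPM. Some of these genes are not reported here. Cgn, Mfsd2a, Gm5506, Eno1, the Y-linked genes and the ends of gene runs were named after their values were seen.

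Chromosomes and the order of genes come from the RefSeq table of GRCm38.p6, matched by symbol or by an unambiguous synonym for 14708 of the 14804 tested genes. Since counts were made on mm9, no coordinates are given. A chromosome score is the median, over its tested genes with a mean log2 CPM above 3, of the log2 CPM minus the gene's median over libraries. GC content and length per gene, from the longest GENCODE transcript, were found for 98.9% of tested genes.

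Replicate numbers are shared by the genotypes in the labels, and a fit with the number as a block was tried as an alternative. Other alternatives fixed beforehand were DESeq2 median-ratio and upper-quartile scaling, no filter, a filter of at least 1 CPM in at least 7 libraries, DESeq2 1.42.0, limma-voom, robust empirical Bayes, terms for Xist and for the mean of non-tumour markers, leaving out each library, and a fold-change minimum. The non-tumour term averaged the markers of endothelial cells, fibroblasts, macrophages and monocytes, T and NK cells, alveolar type 2 cells and club cells. Leaving out RPC tumours 3, 5 and 6, leaving out the 2 RPC tumours with Y-linked counts, and leaving out chromosome 19 genes were added after seeing the data.

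The fit was tested on simulated counts for 14600 genes, drawn from the real means and library sizes with 7 libraries against 7. For this comparison edgeR recovered 21.4% of 98 genes changed 2-fold and 75.3% of 97 genes changed 4-fold, and 2 of its 96 calls were false. Camera called a list moved in the simulation and did not call an unmoved one. Simulated genes varied independently, so this could not test camera on lists whose genes vary together, as in these data. limma-voom recovered 23.5% and 69.1% with 4.21% of calls false, and DESeq2 39.8% and 86.6% with 18.7% of calls false. A 2-fold change was therefore missed more often than not at this spread between tumours, which had a common biological coefficient of variation of 0.555.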

Results

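Gene expression was measured by RNA sequencing in 14 libraries of primary small cell lung cancer from genetically engineered mice. Small cell lung cancer is a neuroendocrine carcinoma, and in these mice the tumour suppressor genes Rb1 and Trp53 were deleted. The labels name 7 libraries of the Rb1/Trp53 genotype, called RP here, and 7 of the Rb1/Trp53/Crebbp genotype, called RPC here. In RPC tumours Crebbp, a histone acetyltransferase and transcriptional coactivator, was deleted as well. The 7 RP libraries held between 10965714 and 23678648 counts in genes and the 7 RPC libraries between 10060969 and 24052799. Log2 depth did not differ detectably between genotypes (exact two-sided permutation test, p = 0.367). The labels number the tumours but do not say that each came from its own mouse, so p-values measure the spread between these samples only. Depths of this order left 14804 of 23284 genes with enough counts to test.

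RPC libraries 3, 5 and 6 stood apart from the other 11. Their scores on the first principal component, which held 45% of the variance, were 136.8, 157.1 and 127.8, against at most 20 in any other library. Markers of macrophages and fibroblasts were low in these 3 libraries. Ctss, a macrophage protease, was at or below 0.105 CPM against at least 63.1 CPM in each of the other 11. Col3a1, a fibroblast collagen, was at or below 0.629 CPM against at least 79.4 CPM. Counts that the comparisons lead with are therefore also given without these libraries, a choice made after the data were seen.

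The deleted genes were read first, as a check of the labels. Crebbp was 76.7 ± 13.9 CPM in RP tumours and 64.8 ± 4.25 CPM in RPC tumours (SD, n = 7 each), a difference in mean log2 CPM of -0.25 with 6 of 7 RPC values under the RP median (exact two-sided permutation test, p = 0.0256; Benjamini-Hochberg adjusted over 4 genes, 0.102). The ranges overlapped, from 59.4 to 97.2 CPM in RP and from 57.9 to 70.0 CPM in RPC. A count over the whole gene includes exons outside a deleted segment and RNA of undeleted cells, and the labels do not name the deleted exons, so the level of Crebbp neither verified nor contradicted the genotype of any library. Rb1, the retinoblastoma gene, was at 154 ± 53.4 and 129 ± 27.2 CPM (exact p = 0.37), and Trp53, which encodes p53, at 26.5 ± 4.96 and 21.6 ± 8.07 CPM (exact p = 0.13; SD, n = 7 each). Ep300, the paralog of Crebbp, was at 171 ± 46.2 and 160 ± 24.9 CPM (exact p = 0.65). For Crebbp even the unadjusted p was over 0.05 without RP tumour 3 (exact p = 0.0554), RP tumour 7 (exact p = 0.0851), RPC tumour 1 (exact p = 0.0589) or the 3 libraries that stood apart (exact p = 0.0818), and with either other scaling (exact p = 0.0589 and 0.0641). For Trp53 the unadjusted exact p was 0.039 without RPC tumour 1, and its difference was 0.026 without the 3 libraries.

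The main question of the design was which genes differ with Crebbp deletion. RPC tumours had higher levels of a block of neighbouring genes on chromosome 4 that holds Mycl1, a MYC-family transcription factor, and of genes along chromosome 19, and lower levels of Trib1, a pseudokinase, Pawr, a pro-apoptotic regulator, and Guk1, a guanylate kinase. Mean Mycl1 was 206.4 ± 121 CPM in RP and 3094 ± 2488 CPM in RPC tumours, and mean Trib1 was 110.2 ± 29.3 and 39.9 ± 7.73 CPM (SD, n = 7 each). Of the genes tested, 161 were higher and 166 lower in RPC than in RP tumours (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 327 in all. Without RPC tumours 3, 5 and 6 the count was 11 (1824 at an unadjusted p under 0.05), of which 9 were among the 327. Each of the 327 kept its direction there, which carries little weight, since they were chosen in libraries that this fit reuses. With the mean of non-tumour markers as a term in the model the count was 7 (1495 at an unadjusted p under 0.05), all of them among the 327.

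Of the 10 genes named by rule as higher, 3 lie on chromosome 4 of the GRCm38.p6 assembly and 5 on chromosome 19. Cap1, which encodes an actin-regulating protein, rose from 217.7 ± 36.1 CPM to 2130 ± 1390 CPM (SD, n = 7 each; log2 fold change 3.29, SE 0.47, edgeR adjusted p = 0.00898). Its neighbours Trit1, a tRNA-modifying enzyme, and Ppt1, a lysosomal thioesterase, rose by 4.38 (SE 0.67) and 2.94 (SE 0.45) on the log2 scale, and Cap1 and Trit1 were above every RP tumour in 7 of 7 RPC tumours. Malat1, a nuclear long noncoding RNA of chromosome 19, went from 257.4 ± 22.4 to 551.7 ± 129 CPM (log2 fold change 1.10, SE 0.15), above every RP tumour in 7 of 7. Atad1, Pola2 (a DNA polymerase alpha subunit), Prpf19 (a splicing factor) and Otub1 (a deubiquitinase), all of chromosome 19, rose as well, Prpf19 from 121.4 to 242.9 CPM and the others by 1.09, 1.16 and 1.01 on the log2 scale. Gnb4, a G protein subunit, and Ccnjl, a cyclin-like gene, rose by 1.38 and 2.99, the latter from a mean of 0.356 CPM.

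Among the 10 named genes that were lower, Trib1 had a log2 fold change of -1.47 (SE 0.18, edgeR adjusted p = 0.00484). Pawr went from 67.2 ± 17.4 to 18.5 ± 6.64 CPM (-1.86, SE 0.23, adjusted p = 0.00484). Both were below every RP tumour in 7 of 7 RPC tumours. Guk1, Kbtbd11, Anxa11 (an annexin), Kcnk1 (a potassium channel), Ptprj (a receptor tyrosine phosphatase) and Manba (a lysosomal mannosidase) fell by between 1.17 and 1.82 on the log2 scale. B4galt5, a galactosyltransferase, fell from 118.8 to 59.4 CPM. Gp2, a glycoprotein, fell from 28.9 ± 22.2 to 0.981 ± 0.882 CPM. All 20 named genes stayed called in each of the 14 fits that left out 1 library (highest edgeR adjusted p = 0.0457). Without RPC tumours 3, 5 and 6, Cap1, Ppt1 and Trit1 stayed called (adjusted p = 0.00473, 0.00473 and 0.0111). Malat1, Trib1, Pawr and Guk1 had adjusted p of 0.0602, 0.0618, 0.0618 and 0.0618 there, at log2 fold changes of 1.03, -1.38, -1.65 and -1.01. The other 13 lost their calls as well (from 0.0661 for Kbtbd11 to 0.137 for Otub1). Among the 11 genes called there were the tight junction genes Tjp3 (-1.70, adjusted p = 0.00473) and Cgn (-1.32, adjusted p = 0.045), which were not called over all 14 libraries. Cgn was chosen after its values were seen.

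**Figure D1:**
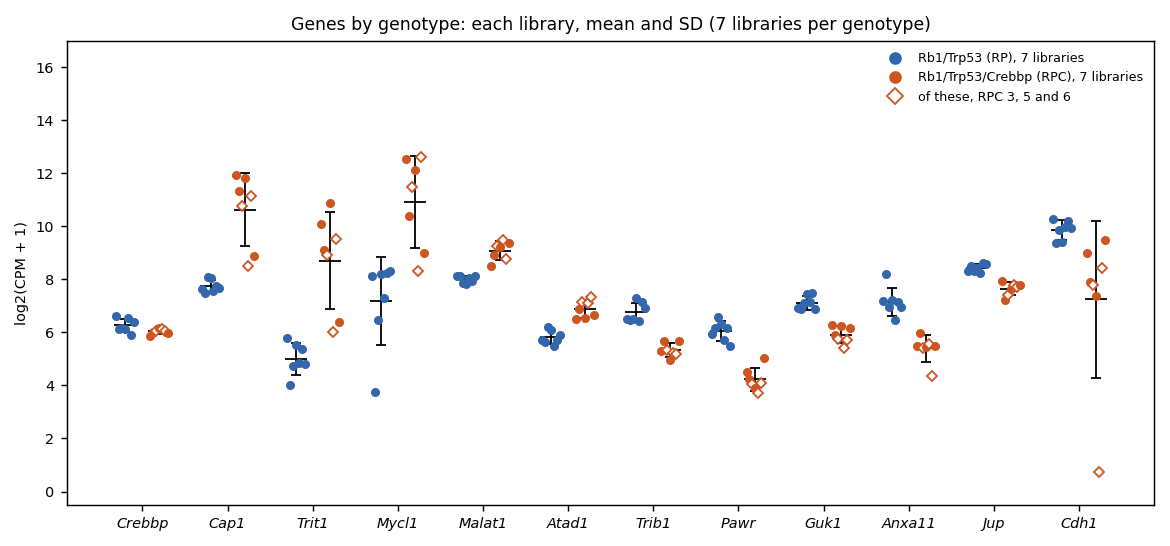
Levels of 12 genes in each library as log2(CPM + 1), with RP tumours on the left of each pair and RPC tumours on the right, and the mean and SD of 7 libraries as black bars. Open diamonds are RPC tumours 3, 5 and 6. Cap1 and Trit1 sit higher in each RPC tumour than in any RP tumour, Trib1 and Pawr sit lower, and Cdh1 is at 0.651 CPM in RPC tumour 5.

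The genes fixed beforehand as regulators of this cancer split. Mycl1 rose (log2 fold change 3.91, SE 0.77, edgeR adjusted p = 0.0246), above every RP tumour in 6 of 7 RPC tumours. Its call was lost without RP tumour 4, 5 or 6 or RPC tumour 3 (adjusted p = 0.05, 0.0504, 0.0569 and 0.0513), and without RPC tumours 3, 5 and 6 (0.091, at a log2 fold change of 3.90, SE 0.755). It was also lost with the term for non-tumour markers (adjusted p = 0.163, log2 fold change 3.88), with a term for Xist (0.0516, 3.80) and without RPC tumours 3 and 4 (0.0837, 3.80). Nfib, a transcription factor gene that is also on chromosome 4, had a log2 fold change of 2.28 (SE 0.58) that missed the threshold (adjusted p = 0.0522). It passed without RP tumour 3 (0.0457), RPC tumour 2 (0.0459) or RPC tumour 7 (0.0285). Its log2 fold change was 1.12 (SE 0.39, adjusted p = 0.265) without RPC tumours 3, 5 and 6 and 0.96 (SE 0.51, 0.572) with the term for non-tumour markers. Cdh1, which encodes E-cadherin, had a log2 fold change of -1.60 (SE 0.72, adjusted p = 0.217). Myc, Mycn, Calca, Syp, Epcam, Vim, Chga and Neurod1 did not pass the threshold (adjusted p from 0.166 to 0.866).

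Around Mycl1, RPC tumours 1, 2, 3, 4 and 6 each had a run of consecutive tested genes of chromosome 4 at least 2 log2 units above the RP mean. No RP tumour had a run that held Mycl1 (5 of 7 against 0 of 7 for runs of at least 4 genes, Fisher's exact test, two-sided p = 0.021). The runs that held Mycl1 had 19, 15, 7, 5 and 5 genes and ended at Trit1 or Ppie on one side. High expression was not limited to them. RPC tumour 2 had another run of 13 genes (Slc2a1 to Hivep3). Beyond Ppie, RPC tumour 3 had runs of 4 genes (Pabpc4 to Akirin1) and 12 genes (Utp11l to Meaf6). RPC tumour 6 had another of 5 genes (Dem1 to Zmpste24), parted from its Mycl1 run by a single gene at 1.96. RPC tumours 3 and 6, which stood apart, had the Mycl1 run and RPC tumour 5 did not. The same test centred on Nfib, for runs of at least 4 genes, gave 0 of 7 against 0 of 7 (Fisher's exact test, p = 1). Shorter runs of 2 genes were found at Nfib in RPC tumour 1 (with Mpdz) and RPC tumour 3 (with Zdhhc21). Nfib alone reached the level in RPC tumour 5, and it did so in no RP tumour. These tests were chosen after the values were seen. Their level was taken from RP tumours, and genes of the Mycl1 block were already called higher in the same libraries. The Fisher test at Mycl1 therefore gave no independent evidence.

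**Figure D2:**
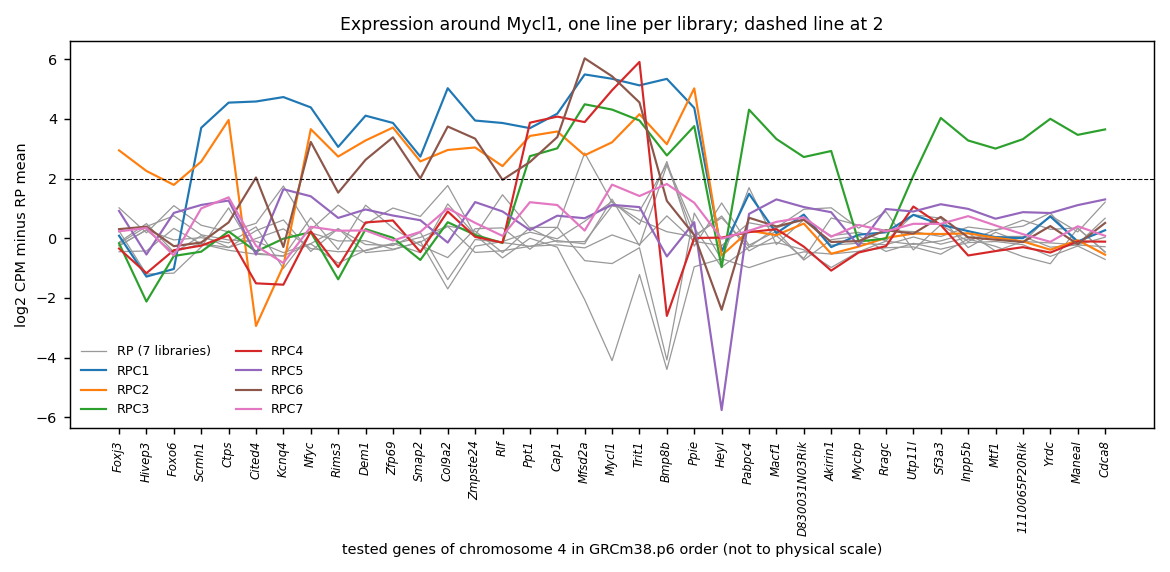
Expression of consecutive tested genes around Mycl1, as log2 CPM minus the mean of RP tumours, in the gene order of GRCm38.p6 and not to physical scale. Grey lines are the 7 RP tumours (each against the mean of the other 6), coloured lines the 7 RPC tumours, and the dashed line marks 2. The lines of RPC tumours 1, 2, 3, 4 and 6 lie above 2 from Ppt1 to Trit1, and that of RPC tumour 1 from Scmh1 to Ppie.

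Genes of chromosome 19 made up 85 of the 161 higher genes and 0 of the 166 lower genes, though only 501 of the 14708 tested genes with a chromosome, or 3.41%, lie there. Their median log2 fold change was 0.46 and 75.8% were positive. A score per library, the median over 400 genes of the distance from each gene's median, averaged -0.27 ± 0.13 in RP and 0.25 ± 0.17 in RPC tumours (SD, n = 7 each; exact two-sided permutation test, p = 0.00117, Benjamini-Hochberg adjusted over 20 chromosomes 0.0234). RPC tumour 1 at -0.11 and RP tumour 7 at -0.02 were the exceptions to the separation. Without RPC tumours 3, 5 and 6 the score differed by 0.44 (exact p = 0.00606) and the median log2 fold change was 0.38, but edgeR called 0 of its genes (167 higher at an unadjusted p under 0.05, against 236 over all libraries). Chromosome 18 scores differed by 0.25 and those of X by 0.14 without passing the adjusted threshold (exact test, adjusted p = 0.0661 for each). For chromosome 18, RP tumours 3 and 4 were low, at -0.48 and -0.67. The other RP tumours scored from -0.06 to 0.09 there and RPC tumours from -0.002 to 0.21. Chromosome 18 held 15 of the 161 higher genes (Fisher's exact test, adjusted p = 0.000756, though genes of a chromosome are not independent). In camera with the preset correlation chromosomes 19 (adjusted p = 3.29e-14), 18 (1.65e-05), X (0.00585), 14 and 15 (0.0207 each), 8 (0.0261) and 9 (0.0419) passed, and no chromosome did otherwise (lowest adjusted p = 0.199 with an estimated correlation, for 19 and X). Among those that passed, the median log2 fold change was negative for chromosomes 15 (-0.17) and 9 (-0.11) and positive for the rest. These chromosome tests were chosen after the data were seen.

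**Figure D3:**
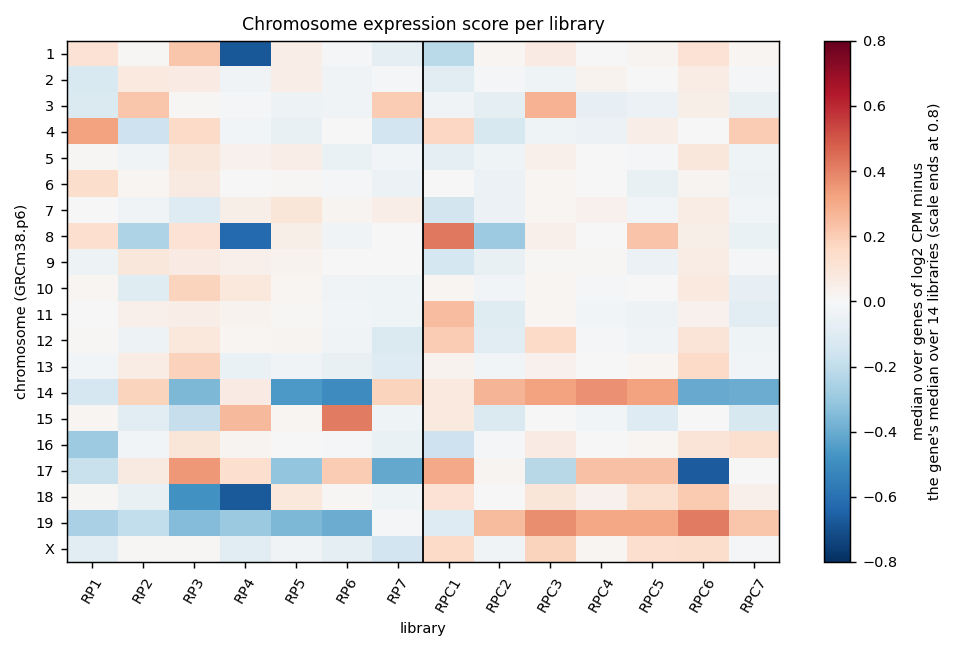
Expression score of each chromosome in each library: the median over its genes with a mean log2 CPM above 3 of the log2 CPM minus that gene's median over 14 libraries, coloured from blue (lower) to red (higher). Chromosome 19 is below 0 in all 7 RP tumours and above 0 in 6 of 7 RPC tumours, while chromosomes 14 and 17 differ between tumours of the same genotype.

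Counts of genes changed with the libraries included. The total of 327 became 117, 898, 113, 137, 51 and 172 without RP tumour 2, 3, 4, 5, 6 or 7 and 65, 186, 190, 158 and 763 without RPC tumour 3, 4, 5, 6 or 7. The 85 genes of chromosome 19 became 32, 131, 31, 32 and 17 without RP tumour 2, 3, 4, 5 or 6 and 21, 55, 48 and 39 without RPC tumour 3, 4, 5 or 6. They became 23 with a term for Xist, 11 without RPC tumours 3 and 4 and 185 with DESeq2. Groups did not overlap in 170 genes, 76 higher and 94 lower, where chance gives 0.0583% of genes.

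The next comparison asked whether junction, adhesion and identity genes moved as groups. Epithelial genes, adherens junction and desmosome genes and tight junction genes were lower as lists in RPC tumours, as were mesenchymal and neuroendocrine genes, and neuronal genes were higher, in tests with a preset correlation of 0.01. All 6 calls were lost when the correlation was estimated from the data (adjusted p = 0.446 with an estimated correlation for each list), and fry, which tests whether genes of a list move one way on balance, called none of them. Mean Cdh1 was 953.5 ± 226 CPM in RP and 315.4 ± 240 CPM in RPC tumours, under every RP value in 6 of 7 but without a call (edgeR adjusted p = 0.217). RPC tumour 5 weighs on the epithelial lists, at a score of -5.98 for epithelial identity against -0.56 in the next lowest library.

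In the epithelial identity list, 24 of 25 genes were lower in RPC tumours (median log2 fold change -0.97, camera adjusted p = 2.78e-06; adjusted p = 0.446 with an estimated correlation), but 0 genes passed the threshold on their own, adjusted over all genes or adjusted over the list alone (edgeR; 8 were lower at an unadjusted p under 0.05). Its members with the smallest p were Elf3, an epithelial transcription factor (-1.33, SE 0.46), and the keratin gene Krt18 (-1.90, SE 0.67), which passed without RPC tumour 5 (adjusted p = 0.0445). Of 22 adherens junction and desmosome genes, 19 had negative fold changes (median -0.58, camera adjusted p = 8.75e-05; adjusted p = 0.446 with an estimated correlation) and 2 fell. These were Jup, which encodes plakoglobin (log2 fold change -0.78, SE 0.12, edgeR adjusted p = 0.00898), and the nectin gene Pvrl2 (-0.91, SE 0.21, adjusted p = 0.0379), with 4 falling when adjusted over the list alone. Ctnnb1, which encodes beta-catenin, was at 1220 ± 272 and 835 ± 125 CPM (adjusted p = 0.0874). Of 38 tight junction genes, 23 had negative values (median -0.30, camera adjusted p = 0.0164; adjusted p = 0.446 with an estimated correlation). The scaffold gene Magi1 rose (1.71, SE 0.41, edgeR adjusted p = 0.0442), against the direction of its list, and the list alone gave 2 higher and 6 lower, Tjp3 (-2.02, SE 0.53) among these. Tjp3 passed over all genes without RP tumour 3 (adjusted p = 0.0495) or RPC tumour 5 (0.00414). Magi1 lost its call without RP tumour 2, 4, 5, 6 or 7 or RPC tumour 1, 3, 4 or 5 (adjusted p from 0.0633 to 0.1). Pvrl2 lost its call without RP tumour 1, 4, 6 or 7 or RPC tumour 2, 3, 4, 5 or 6 (from 0.0523 to 0.0793), and Jup kept its own in all 14 such fits. Jup lost its call, at log2 fold changes from -0.79 to -0.73, without RPC tumours 3, 5 and 6 (0.104), with the term for non-tumour markers (0.12) and without RPC tumours 3 and 4 (0.0626).

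Mesenchymal genes had a median of -0.54 over 18 genes, with Fn1 (fibronectin) at -1.16 and Tgfb1 at -1.29 and 0 genes called by edgeR (2 lower at an unadjusted p under 0.05; camera adjusted p = 0.025; adjusted p = 0.446 with an estimated correlation). Their median without RPC tumours 3, 5 and 6 was 0.04, opposite in sign to the test, and the call was lost (adjusted p = 0.831). It was lost without RPC tumour 3 (0.0748) or 6 (0.0782) alone. Neuroendocrine genes had negative values in 22 of 29 (median -0.29, camera adjusted p = 0.0392; adjusted p = 0.446 with an estimated correlation), with Foxa2 at -0.69 (SE 0.21) and 0 genes called over all genes or adjusted over the list alone (edgeR; 5 lower at an unadjusted p under 0.05). That call was lost without RP tumour 2, 5 or 6 (0.102, 0.0662 and 0.0549) or RPC tumour 1 or 2 (0.105 and 0.0977). Neuronal genes had positive values in 16 of 26 (median 0.51, camera adjusted p = 0.0206; adjusted p = 0.446 with an estimated correlation). Gap43, a growth cone protein, rose (2.63, SE 0.61, edgeR adjusted p = 0.0405) and the RNA-binding gene Celf3 fell (-1.13, SE 0.22, adjusted p = 0.0244). Celf3 lost its call without RP tumour 4 or 6 or RPC tumour 3 (adjusted p from 0.05 to 0.0516), without RPC tumours 3, 5 and 6 (0.179), with the term for non-tumour markers (0.227, log2 fold change -0.88) and without RPC tumours 3 and 4 (0.0623). Gap43 lost its call without RP tumour 2, 4, 5, 6 or 7 or RPC tumour 3, 4, 5 or 6 (from 0.0559 to 0.0926). The log2 fold change of Gap43 was 1.73 without RPC tumour 5, 1.66 without RPC tumours 3, 5 and 6 (adjusted p = 0.187) and 1.57 with the term for non-tumour markers (0.373). The neuronal call was lost without RPC tumour 5 (adjusted p = 0.0558) and without the 3 libraries that stood apart (0.224). The calls of the epithelial (2.32e-14), adherens (7.99e-06), tight junction (0.00358) and neuroendocrine (0.00341) lists held without these 3 libraries in camera with the preset correlation. Neither the estimated correlation nor fry was run without them, so whether these calls outlast either is not known.

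**Figure D4:**
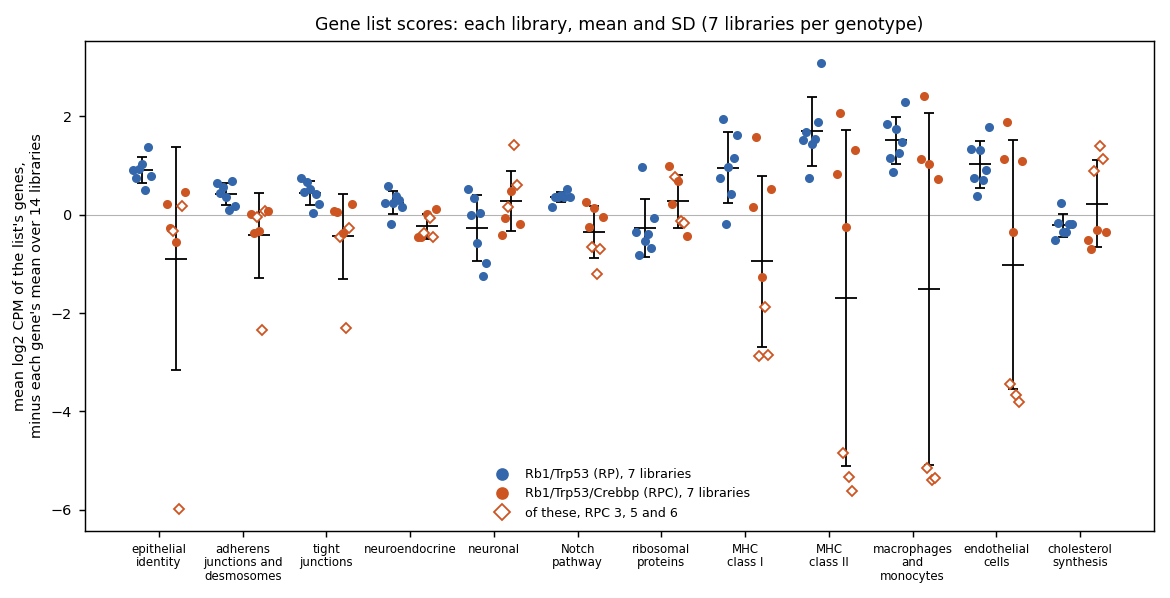
Scores of 12 gene lists per library, the mean over genes of the log2 CPM minus each gene's mean over 14 libraries, with the mean and SD of 7 libraries per genotype in black. Open diamonds are RPC tumours 3, 5 and 6. Macrophage scores of these 3 lie between -5.40 and -5.15 and those of all other libraries at or above 0.73.

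The last group of tests covered 31 further lists. With the preset correlation the lists of ribosomal protein and oxidative phosphorylation genes were called higher in RPC tumours, and those of Notch pathway, hypoxia and antigen presentation genes and of most non-tumour cell types lower. None of these calls held with the correlation estimated (adjusted p = 0.446 with an estimated correlation or more). Over all 37 lists tested, 20 were called lower and 5 higher with the preset correlation. With the correlation estimated 0 were called (lowest adjusted p = 0.446 with an estimated correlation; 0 at an unadjusted p under 0.05). By fry 0 were called for 1 direction (13 at an unadjusted p under 0.05) and 16 for changes either way. The preset correlation called 11 without RPC tumours 3, 5 and 6.

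Notch pathway genes had a median of -0.78 over 21 genes (camera adjusted p = 0.00191; adjusted p = 0.446 with an estimated correlation), with 6 lower adjusted over the list alone. The ligand gene Dll1 fell (-1.31, SE 0.32, edgeR adjusted p = 0.0498), and Nrarp, a Notch feedback gene, was at -0.78 (SE 0.19, adjusted p = 0.0501). Dll1 lost its call without RP tumour 1, 2, 4, 5 or 6 or RPC tumour 1, 2, 3, 4, 5 or 6 (from 0.056 to 0.101), and Nrarp passed without RP tumour 3 (0.0317) or RPC tumour 2 (0.0486) or 7 (0.0344). Hypoxia and glycolysis genes had a median of -0.54 over 18 genes (camera adjusted p = 0.00157; adjusted p = 0.446 with an estimated correlation). Egln3, a prolyl hydroxylase induced by hypoxia, fell from 192 ± 99.7 to 45.3 ± 16.0 CPM (edgeR adjusted p = 0.0114). Its call was lost without RPC tumours 3, 5 and 6 (0.091), with the term for non-tumour markers (0.122) and without RPC tumours 3 and 4 (0.0619). Ankrd37 fell by 0.99 (adjusted p = 0.0462), a call lost without any RP tumour but 3 or any RPC tumour but 1 or 7 (from 0.05 to 0.0973). All 26 ribosomal protein genes had positive values (median 0.44, camera adjusted p = 3.44e-05; adjusted p = 0.446 with an estimated correlation) with 0 called by edgeR (4 higher at an unadjusted p under 0.05). Positive values were also found in 20 of 21 oxidative phosphorylation genes (median 0.34, camera adjusted p = 8.75e-05; adjusted p = 0.446 with an estimated correlation), of which Ndufb8, a chromosome 19 gene, rose by 0.89 (edgeR adjusted p = 0.0275). Ndufb8 lost its call without RP tumour 2, 4, 5 or 6 or RPC tumour 3 or 6 (from 0.0504 to 0.0648), and its log2 fold change was 0.54 both without RPC tumours 3, 5 and 6 (adjusted p = 0.22) and with the term for non-tumour markers (0.272). With the preset correlation, the only one run there, these 4 lists were also called without RPC tumours 3, 5 and 6 (0.0235, 0.00341, 3.89e-07 and 0.0414). Oxidative phosphorylation genes lost their call with the term for non-tumour markers (adjusted p = 0.107, median 0.09).

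Histone acetyltransferase and deacetylase genes were not called as lists (camera adjusted p = 0.345 and 0.399). Kat5, on chromosome 19, rose (0.74, SE 0.16, edgeR adjusted p = 0.0324) and Hdac5 fell (-0.68, SE 0.14, adjusted p = 0.0246), while Hdac1 and Hdac2 were at 0.28 and 0.60 without a call. Kat5 lost its call without RP tumour 2, 4, 5 or 6 or RPC tumour 3, 4, 5 or 6 (from 0.0536 to 0.0757) and Hdac5 without RP tumour 4, 5 or 6 or RPC tumour 3 (from 0.05 to 0.0536). Kat5 and Hdac5 also lost their calls without RPC tumours 3, 5 and 6 (0.177 and 0.161), with the term for non-tumour markers (0.203 and 0.174) and without RPC tumours 3 and 4 (0.106 and 0.0745). Hdac2 passed without RP tumour 3 (0.0233). The median and the test of the deacetylase list were positive and its mean was -0.001. Of the cAMP and CREB responsive genes (camera adjusted p = 0.18), Junb, an immediate early transcription factor, fell (-1.12, edgeR adjusted p = 0.0475). Of p53 targets (camera adjusted p = 0.197), Trp53inp1 fell (-1.33, edgeR adjusted p = 0.0472). Junb was called only without RP tumour 3 or RPC tumour 1 or 6 (lost calls from 0.0507 to 0.101), and Trp53inp1 only without RP tumour 3 or RPC tumour 7 (from 0.0535 to 0.1). The driver list was not called (0.911, median -0.16, mean -0.09 and a positive test statistic). Unfolded protein genes were not called (0.728, median -0.08, mean 0.08 and a negative test statistic). Cell cycle genes were called higher (median 0.19, camera adjusted p = 0.012; adjusted p = 0.485 with an estimated correlation), as were cholesterol synthesis genes (median 0.71, camera adjusted p = 0.016; adjusted p = 0.485 with an estimated correlation). Without RPC tumours 3, 5 and 6 both had negative medians of -0.05 and -0.18 and no call. Each of the 3 libraries that stood apart held 154 CPM or more of Cyp51, which encodes a sterol demethylase of that pathway, and each other library 67.1 CPM or less.

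Antigen presentation genes of MHC class I (14 of 14 negative, median -1.18), MHC class II (8 of 8, median -1.47) and the interferon response (20 of 21, median -0.95) were called lower (camera adjusted p = 2.93e-05, 7.78e-05 and 2.78e-06; adjusted p = 0.446 with an estimated correlation for each). None of their genes passed in edgeR (3, 0 and 4 were lower at an unadjusted p under 0.05). H2-D1 was at -1.57 (SE 0.79) and Cd74 at -1.37 (SE 1.19). The medians of these lists without RPC tumours 3, 5 and 6 were -0.52, -0.70 and -0.32, with camera adjusted p of 0.00518, 0.00518 and 0.017 at the preset correlation, the only one run there. With the term for non-tumour markers the interferon list lost its call (0.409), and the MHC lists had adjusted p of 0.044 and 0.0308. Integrin genes (median -0.27, camera adjusted p = 0.00596; adjusted p = 0.446 with an estimated correlation) lost their call without these libraries (0.855).

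Markers of macrophages, endothelium, fibroblasts, smooth muscle and pericytes, T and NK cells, B and plasma cells, club cells and ciliated cells were called lower. Their medians were -0.94, -0.74, -0.37, -1.04, -0.86, -2.39, -0.995 and -0.55 (camera adjusted p = 2.78e-06, 6.83e-05, 0.012, 0.00153, 0.0159, 0.038, 0.016 and 0.0233; adjusted p = 0.446 with an estimated correlation for all but ciliated cells, 0.461 with an estimated correlation). Alveolar type 2 genes were called lower (0.00147; adjusted p = 0.446 with an estimated correlation) with a median of 0.19 and a mean of 0.10, opposite in sign to the test, and Sftpc was at 354 ± 295 and 365 ± 619 CPM. None of these 9 lists was called without RPC tumours 3, 5 and 6 (adjusted p from 0.256 to 0.855). Ciliated cell markers lost their call without RP tumour 1 (0.0618) or 7 (0.0561) or RPC tumour 6 (0.0782). B and plasma cells lost theirs without RP tumour 1 (0.0599) or 7 (0.0637) or RPC tumour 3 (0.0585), 5 (0.0911) or 6 (0.0791). Club cells lost it without RPC tumour 5 (0.0889), fibroblasts without RPC tumour 6 (0.0535), cholesterol synthesis without RPC tumour 5 (0.119) or 6 (0.0782), and cell cycle genes without RPC tumour 6 (0.0782). Alveolar type 1, tuft, neutrophil, erythroid, mesothelial and cardiac lists were not called (0.0869, 0.228, 0.0869, 0.0548, 0.0854 and 0.139). All of these but the tuft list passed in some fits without 1 library. For alveolar type 1 cells these left out RPC tumour 2 (0.0174) or 7 (0.0462), for neutrophils RPC tumour 1 (0.0498), for erythroid cells RP tumour 3 (0.0323) or 4 (0.0479) or RPC tumour 4 (0.0379), for mesothelium RPC tumour 2 (0.0163) and for cardiac muscle RP tumour 4 (0.0479). Sox9, listed with tuft cell genes and better known as a progenitor transcription factor, rose 24.2-fold from a mean of 0.601 CPM (edgeR adjusted p = 0.0255). It lost its call without RP tumour 2, 4, 5 or 6 or RPC tumour 3 (from 0.05 to 0.0575). Its log2 fold change was 3.14 without RPC tumour 5, 2.27 without RPC tumours 3, 5 and 6 (adjusted p = 0.161) and 2.34 with the term for non-tumour markers (0.266). Lists of basal, skeletal muscle, adipocyte, hepatocyte and glial genes had fewer than 3 testable members.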

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

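In this part, tests of Mycl1 runs outside the 3 libraries that stood apart, of the chromosome 19 score and of stromal and epithelial lists were chosen after the result was seen; the other tests were set before theirs was.

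In 24 of 252 groups of 7 values examined, 1 library lay farther from its neighbour, as a share of the range, than Dixon's 95% critical value; chance alone gives about 5% of groups. RPC tumour 5 was that library in 9 of the 24, most of them epithelial genes or lists. The gap took 0.784 of the range for Cdh1, 0.847 for Epcam, 0.72 for Tjp3, 0.803 for Krt18 and 0.792 for Krt7. For the list scores it took 0.842 for epithelial identity, 0.809 for adherens junctions and desmosomes and 0.729 for tight junctions. Cdh1 was at 0.651 CPM there and at 165 CPM or more in each other RPC tumour. Hdac1 was highest in the same tumour, at 396 CPM (0.595).

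RP tumour 3 was highest for Myc at 654 CPM, where the next RP tumour was at 22.7 CPM (gap 0.848), for Hdac2 (0.656), Rps6 (0.641) and the ribosomal protein score (0.575). RP tumour 5 was highest for Mycn, at 522 CPM against 34.1 CPM in the next (0.616). RP tumour 2 was lowest for Mycl1 at 12.6 CPM (0.601), Nfib (0.69) and the fibroblast score (0.636) and highest for Anxa11 (0.574) and Syp (0.662). RP tumour 4 was lowest for Kcnk1 (0.582). RPC tumour 6 was lowest for Anxa11 (0.643), Tgfb1 (0.751) and Junb (0.587), and RPC tumour 1 for the chromosome 19 score (0.635).

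Y-linked transcripts, used only to choose the 2 tumours left out in some fits, were counted in RPC tumours 3 and 4. Ddx3y had 683 and 595 counts there and at most 2 counts in any other library, and Xist had 17 and 70 counts against at least 17706 elsewhere. No RP tumour had such counts. By these transcripts RPC tumours 3 and 4 read as male and all RP tumours as female, so sex and genotype were partly confounded.

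The first pattern is the block of genes around Mycl1 that was high in 5 of 7 RPC tumours. A low share of RNA from non-tumour cells in the 3 libraries that stood apart is argued against, because 3 of the 5 tumours with the run (RPC tumours 1, 2 and 4) are outside those 3 libraries. A candidate explanation is a gain in copies of a shared interval. No other place on any chromosome had a run of at least 4 such genes in more than 1 RPC tumour. A run shared by 5 elsewhere had been set to count against a gain. That outcome cannot single out a gain in copies, since any cause confined to the interval would give it too. DNA was not analysed here, so whether copies were gained, and whether they follow from Crebbp deletion, stays open.

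The second pattern is the higher expression of chromosome 19 genes in RPC tumours. GC content and gene length are argued against, since the median log2 fold change less that of matched genes was 0.48, where the other 19 chromosomes had an SD of 0.0979. A low share of non-tumour RNA is argued against as the whole cause: with a term for it the median went from 0.46 to 0.43. The median SE of these genes went from 0.27 to 0.30 and the calls from 85 to 0. In edgeR, 175 were higher at an unadjusted p under 0.05 with the term, against 236 over all libraries without it. What ended the calls was not tested. Chance is argued against by the score per library (exact two-sided permutation test, adjusted p = 0.0234 over 20 chromosomes) and not by the count of calls, where 1 of 100 splits, the real one, called 85 and the highest other called 0, as no other split called more than 3 genes of any chromosome. A change in the dosage of the chromosome, lower in RP tumours or higher in RPC tumours, may account for it, as the lowest median over 5 equal stretches was 0.31; the direction, the cell fraction and the tie to Crebbp stay open.

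The third pattern is the lower level of non-tumour, MHC and epithelial lists in RPC tumours. Whether a low share of non-tumour RNA in RPC tumours 3, 5 and 6 explains the stromal, blood and immune part cannot be told from the scores: 9 of 9 such lists had all 3 libraries below each of the other 11, which restates what set them apart, and of the 6 called over all libraries 0 were called without them; the labels, which name primary tumours, do not tell purer tissue from cells grown outside the animal. For MHC class I and class II genes the explanation cannot be told apart from a change in the tumour cells, since medians of -0.51 and -0.60 with a term for non-tumour markers lie between the values set for each outcome. For epithelial identity it is argued against as the whole cause: the median stayed at -0.86 with the term (camera adjusted p = 0.000243 with the preset correlation; over all libraries and without the term, adjusted p = 0.446 with an estimated correlation and 0.117 by fry). The score per library, which needs no correlation between genes, was lower in 4 of 4 remaining RPC tumours than in any RP tumour without RPC tumours 3, 5 and 6 (exact two-sided permutation test, p = 0.00303), so an effect of Crebbp deletion on epithelial genes remains open as a hypothesis.

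As for the totals, chance is argued against for the number of genes called. Of 100 splits of the 14 libraries, out of 1716 possible, the real one gave 327 and the highest other gave 3. Of the others, 17 kept the 3 libraries that stood apart on one side. The real split also placed these 3 libraries and both tumours with Y-linked counts among RPC tumours, so it does not by itself tie the count to Crebbp. Chance cannot be excluded for the number of lists called with the preset correlation, as 8 of the 100 splits gave 25 or more. Splits other than the real one had a median of 11. The highest of them gave 28, a split with the 3 libraries that stood apart on one side.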

How the results depend on the processing

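The settings without RPC tumours 3, 5 and 6, without the 2 tumours with Y-linked counts and without chromosome 19 genes were chosen after seeing the data; all other settings were fixed before. Both other scalings, the filter of 1 CPM, no filter and robust empirical Bayes kept the counts of called genes within 1.5 times of 327, and no list changed its direction under them. B and plasma cells lost their call with no filter (adjusted p = 0.0569) and with the filter of 1 CPM (0.0744), and neutrophils (0.0191) and erythroid cells (0.0068) gained one with no filter. Of the genes named, Dll1 (0.0573), Magi1 (0.0509), Junb (0.0537), Trp53inp1 (0.0515) and Ankrd37 (0.0512) lost their calls with no filter, and Dll1 (0.0524) and Junb (0.0503) with upper-quartile scaling. For results that changed, the cause was not tested except where named. Depth and the spread between tumours limit small changes: 2-fold changes were mostly missed in simulated data.

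Counts moved with the term for non-tumour markers, the libraries and the tool. DESeq2 called 1431 genes, 689 higher and 742 lower, with 326 of the 327 among them, and in simulated data it had the highest share of false calls. It also called Nfib (0.000892), Tjp3 (0.00253), Ctnnb1 (0.0153), Elf3 (0.0341), Krt18 (0.0267), Foxa2 (0.0222), Nrarp (0.00545) and Rps6 (0.0094). limma-voom called 503, with 292 lower. It ended the calls of Sox9 (0.103, log2 fold change 3.35), Gap43 (0.087), Trp53inp1 (0.079), Ankrd37 (0.0672), Magi1 (0.0548) and Dll1 (0.0516) and gave calls to Tjp3 (0.0397) and Nrarp (0.0369). Nrarp also passed with the filter of 1 CPM (0.0494) and robust empirical Bayes (0.0482). The fold-change minimum left 207, with 79 higher, by its construction. A term for Xist gave 82, 41 in each direction, and the tumours with Y-linked counts left out 37, with 20 higher and 17 lower. The Xist term ended the calls of Mycl1 (0.0516), Magi1 (0.101), Gap43 (0.0633), Dll1 (0.086), Kat5 (0.0693), Junb (0.0869), Trp53inp1 (0.0804), Ankrd37 (0.0659) and Ndufb8 (0.0642). Without the tumours with Y-linked counts Otub1 (0.0622) and Kcnk1 (0.0525), of the genes named by rank, lost their calls. Every called gene named as a list member lost its call in that setting (0.0619 for Egln3 to 0.158 for Magi1), without RPC tumours 3, 5 and 6 (0.091 to 0.297) and with the term for non-tumour markers (0.12 to 0.373). A term for non-tumour markers gave 7, with 3 higher and 4 lower, 6 of them (Cap1, Trit1, Ppt1, Pawr, Kbtbd11 and Trib1) among the 20 genes named by rank, at a median SE over genes of 0.30 where the model without it had 0.27. The other 14 lost their calls (0.0748 to 0.163). Without RPC tumours 3, 5 and 6 it was 11, with 3 higher and 8 lower. Without chromosome 19 genes it was 113, with 33 higher and 80 lower: fewer called genes also raise the adjusted p of the rest. Magi1, Pvrl2, Gap43, Dll1, Junb, Trp53inp1 and Ankrd37 lost their calls there (0.0526 to 0.0652). Leaving out 1 library gave 51 to 898 genes, 24 to 481 higher and 27 to 434 lower.

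The replicate number as a block gave 74 genes, 23 higher and 51 lower, 62 of them among the 327. Correlations of same-numbered tumours lay between -0.054 and 0.322, with a mean of 0.115 against -0.018 for other numbers, and 5 of 14 libraries correlated best with their own number. Since pairs 1, 2, 4 and 6 were under 0.1, the numbers were not taken to pair tumours. With the block the adjusted p was 0.152 for the mesenchymal list, 0.101 for the neuronal list and 0.755 for the driver list, the last with its direction reversed, as for Neurod1 at 0.00 and Sftpc at -2.36. It also ended the calls of Pola2 (0.0556), Prpf19 (0.0544), Jup (0.0518), Mycl1 (0.0682), Egln3 (0.07), 11 other genes named as list members (0.0606 to 0.126) and the alveolar type 2 (0.153), fibroblast (0.3) and smooth muscle (0.0565) lists, and left 12 higher genes of chromosome 19. It brought calls for the neutrophil (0.0227) and cardiac muscle (0.0327) lists.

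The difference for Crebbp was -0.23 log2 CPM with either other scaling (exact p = 0.0589 and 0.0641), -0.24 with edgeR (unadjusted p = 0.0635 in place of the exact test), -0.25 without the 3 libraries that stood apart, and -0.30 to -0.19 without 1 library. That for Trp53 was 0.026 without the 3 libraries, which reversed it, and -0.50 to -0.25 without 1 library.

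For the 6 main lists, all calls were lost with an estimated correlation (adjusted p = 0.446 for each) and with fry, at 0.117 for tight junctions, 0.0898 for adherens junctions and desmosomes, 0.117 for epithelial identity, 0.119 for mesenchymal genes, 0.0898 for neuroendocrine genes and 0.147 for neuronal genes. With a term for non-tumour markers the call was lost for tight junctions (0.107), mesenchymal (0.969) and neuronal genes (0.409), and without the 3 libraries for mesenchymal (0.831) and neuronal genes (0.224). The mesenchymal call was lost without the tumours with Y-linked counts (0.0724) and the neuroendocrine call without chromosome 19 genes (0.0557). Without 1 library the adjusted p ranged from 0.00598 to 0.0782 for mesenchymal, 0.0147 to 0.105 for neuroendocrine and 0.00446 to 0.0558 for neuronal genes.

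Other lists reversed mainly with the term for non-tumour markers. That term is made of the endothelial, fibroblast, macrophage, T and NK, alveolar type 2 and club markers themselves. Changes in those lists under it were therefore built in. With the term, directions turned for integrins (adjusted p = 0.408), drivers (0.694), cell cycle (0.499), cholesterol synthesis (0.0263, called lower), alveolar type 2 (0.115), alveolar type 1 (0.115), ciliated (0.706), endothelial (0.351), neutrophil (0.945), T and NK (0.969), B and plasma (0.969) and mesothelial genes (0.263). Calls were lost with the term for interferon (0.409), oxidative phosphorylation (0.107), club (0.408), fibroblast (0.966), smooth muscle (0.354) and macrophage genes (0.585). Without the 3 libraries directions turned for drivers (0.833), cell cycle (0.855), cholesterol synthesis (0.112) and mesothelium (0.716). Calls of B and plasma cells were also lost with the Xist term (0.0598), without the tumours with Y-linked counts (0.152) and without chromosome 19 genes (0.0802). Those of ciliated cells were lost with the Xist term (0.0504) and without the tumours with Y-linked counts (0.0803), where erythroid cells gained one (0.0249), and that of club cells without chromosome 19 genes (0.0802). Drivers also turned without chromosome 19 genes (0.883) and with fry (0.751), and unfolded protein genes with the Xist term (0.893) and without the tumours with Y-linked counts (0.46). Without 1 library the adjusted p was 0.676 to 0.981 for drivers and 0.29 to 0.98 for unfolded protein genes.

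Genes that reversed were not called in any direction. In DESeq2 Mycn was at 0.04 and Myc at 0.20, and in limma-voom Neurod1 at 1.27 and Sftpc at -2.41. With the Xist term Sftpc was at -0.12. With the non-tumour term Trp53 was at 0.07, Vim 0.17, Sparc 0.12, Pecam1 0.35, Sftpb 0.31 and Mki67 -0.07. Without the 3 libraries Trp53 was at 0.03, Vim 0.04, Sparc 0.09, Lyz2 0.26, Pecam1 0.15, Sftpb 0.44 and Mki67 -0.06. Without the tumours with Y-linked counts Ep300 was at 0.01 and Sftpb at 0.12. Without 1 library the ranges were -3.13 to 0.04 for Mycn, -2.98 to 0.21 for Myc, -0.40 to 0.08 for Chga, -1.12 to 0.26 for Neurod1 and -1.12 to 0.43 for Sftpc; Myc turned without RP tumour 3 and Mycn without RP tumour 5, the tumours in which each was highest.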

Other observations

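RP tumours differed in which MYC-family gene was high, while Mycl1 was the highest of Mycl1, Myc and Mycn in each RPC tumour. Mycl1 ranged from 315 to 6228 CPM in RPC tumours and from 12.6 to 316 CPM in RP tumours. RP tumour 3, with Myc at 654 CPM, and RP tumour 5, with Mycn at 522 CPM, held more of these genes than any RPC tumour, in which Myc reached 49.8 CPM and Mycn 33.4 CPM. Nfib reached 2408 CPM in an RPC tumour and stayed at or under 240 CPM in RP tumours.

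The gene with the largest drop in the table, Gm5506, lies outside the naming rule and was chosen after its values were seen: its log2 fold change was -7.14 (edgeR adjusted p = 4.08e-06), and it was still called without RPC tumours 3, 5 and 6 (-7.05, adjusted p = 0.00193). Gm5506 was at 57.1 CPM or more in each RP tumour and at 1.36 CPM or less in each RPC tumour. It is an enolase-like predicted gene that can share reads with Eno1, so its absolute level is uncertain. Eno1 was at 42.3 to 165.6 CPM in RP and 25.9 to 70.3 CPM in RPC tumours, so no rise in Eno1 matched the drop. Chromosome scores of single tumours also differed from those of most others of their genotype: RP tumour 4 was at -0.68 for chromosome 1 and -0.67 for chromosome 18, RP tumour 6 at 0.41 for chromosome 15, and RPC tumour 6 at -0.67 for chromosome 17.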
